A study of Mus musculus with 18 samples.

How the data were processed

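Total RNA from frontal cortex, striatum and midbrain of mice treated with MPTP or saline was hybridised to Affymetrix mouse expression arrays, 1 array per sample, per the labels' protocols. The deposited values were log2 expression summaries per probe set that the authors had made by RMA, per the submitters' processing notes, and the RMA version was not given in the sources used here. RMA corrects the background, brings the arrays to one distribution and summarises the probes of a probe set, so that a shift of all genes in one group would not be visible. The log base was read from the values, which ran from 2.48 to 14.2. All 18 arrays and 45101 probe sets were used, and no column was left out. Of the probe sets, 34958 named 1 gene, 932 named several and 9211 were not listed with a gene, and no gene was named from the last 2 kinds. For 34754 probe sets the symbol was looked up by Entrez ID in the mouse reference annotation GRCm38.p6, used for names only and without coordinates, and 204 kept the symbol of the array annotation. The number of arrays, 3 per group, limits the precision of every value.

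Each of 18194 genes was represented by its probe set of highest mean over the 18 arrays, and 9012 genes had more than 1 probe set. A gene was tested if its mean in at least 1 region reached the median of all probe sets (the 50th percentile, 5.18 on the log2 scale), which left 11741 genes. No detection call was used, and the lower limits for genes with a group below that value were chosen after the data were seen. Of 118 other probe sets of the genes named in a single region 96 had the same sign as the one used, as did 65 of the 74 at or above the filter value, 37 of them with an unadjusted p under 0.05. Limma 3.58.1 in R 4.3.3 was fitted with a mean for each of the 6 groups over all 18 arrays, with moderated variances that follow an intensity trend, and p-values were adjusted by Benjamini-Hochberg within each contrast. Genes with an adjusted p under 0.05 were called. The 12 residual degrees of freedom rose to 23.2 after moderation. For the mean over the regions the animal, taken as treatment and replicate number, was a random block with an estimated correlation of 0.00558, since arrays of 1 animal are not independent, although the labels do not say that a number marks the same animal in each region. Differences between regions in the response to MPTP were tested as interaction contrasts.

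The groups, tests, filter, alternatives, naming rule and 43 gene lists were fixed before the data were examined. The lists held 985 entries, of which 891 were on the array (4 through an older symbol) and 724 were tested. They covered cell types, pathways and complexes, and were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a contrast. The list tests used no block by animal, also for the mean over the regions. No list passed with an estimated correlation in any contrast. The median, the mean and the camera direction had one sign for all 88 list results past the threshold. Named genes were, for each region and for the mean over regions, the 12 largest rises and 12 largest falls among called genes, and where fewer than 10 genes were called also the 10 of smallest p, as values. For interactions they were the 6 called genes of smallest p, or the 3 of smallest p if none was called. For saline regions they were the 5 largest differences each way, and in each list up to 4 members, called ones first. Th, Slc6a3, Slc18a2 and Ddc were always named in midbrain and striatum and Gfap in every region, and predicted genes were counted but passed over.

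The procedure was tested on simulated data made from the measured means and spreads of the 11741 genes, with 200 of them changed. At a true log2 change of 1 it recovered 95.5% of the changed genes in frontal cortex, 100% in striatum and 97.2% in midbrain, and at 0.5 it recovered 78.9%, 66.7% and 73.7%. For the differences between regions at 0.5 it recovered 37.8% for striatum minus cortex, 28.8% for midbrain minus cortex and 40% for midbrain minus striatum. False calls were 9 of 191 calls in frontal cortex, 16 of 194 in striatum and 3 of 186 in midbrain. The noise was drawn independently for each gene, with 1 spread per gene for all groups. Variation shared by the genes of an array was thus not simulated, and these shares do not cover it. The alternatives were no filter, a filter at the 75th percentile, quantile normalization a second time, centring on the array median, the mean over the probe sets of a gene, variances without trend or with robust estimation, array weights, the arrays of a region alone, blocks by replicate number or animal, and leaving out each array in turn. After the data were seen, 4 more were added: 1 mean over the regions per animal for the mean over regions, the interquartile range of the array as a covariate, leaving out the saline array of lowest interquartile range in each region, and every probe set tested on its own.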

Results

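Gene expression was measured in 3 brain regions of C57BL/6J mice that had been treated with MPTP or with saline. MPTP is a neurotoxin that is converted in the brain to a compound taken up by dopaminergic neurons, and it is used to model Parkinson's disease in mice. The males, 14 weeks old, received 30 mg/kg MPTP or saline once a day for 5 days, and the tissue was collected 4 days after the last injection. Frontal cortex, striatum and midbrain each gave 3 arrays per treatment, so that 18 arrays fell into 6 groups of 3. The interquartile range of the log2 values on an array lay between 3.37 and 3.65 and the array median between 5.14 and 5.21. Arrays of one group correlated at 0.991 to 0.997 over all probe sets, and the saline midbrain arrays, at 0.991 to 0.994, had the lowest values.

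The saline animals were compared first, to describe how the regions differ without toxin. By the reported values, saline striatum exceeded saline frontal cortex most in the orphan receptor Gpr6 (9.55 ± 0.08 against 3.62 ± 0.38, mean and SD of log2 values, n = 3), in the dopamine receptor Drd2, in Ido1, in the choroid plexus transport protein Ttr and in the signalling regulator Rgs9 of medium spiny neurons. The cortex exceeded the striatum most in the neuropeptide Vip, in Cbln2, in Nrn1, in Fmod and in Myl4. Saline midbrain stood above frontal cortex most in the dopamine transporter Slc6a3 (9.40 ± 0.26 against 3.79 ± 0.19, n = 3), in Shox2, in Agt, in the dopamine-synthesis enzyme Ddc and in Mab21l1, and below it most in Neurod6, Crym, Egr3, Ddn and Itpka. Against the striatum, the midbrain was higher most in the vesicular glutamate transporter Slc17a6, in Slc6a3, Shox2, Calb2 and Mab21l1, and lower most in Gpr6, the dopamine receptor Drd1, Ankrd63, Crym and Ido1. Values below 5.18, the filter value for dim genes, were not shown to be above background. Where all arrays of one group lay below it, the difference is also given as a lower limit, the distance of the other group's mean from 5.18, and the order of such genes is that of the values alone. In saline cortex this held for Gpr6, Drd2 and Ido1 (at least 4.37, 5.06 and 3.54 higher in striatum) and for Slc6a3, Shox2 and Mab21l1 (at least 4.22, 3.54 and 2.44 higher in midbrain). The last 3 lay below it in saline striatum too, with the same limits. In saline midbrain it held against cortex for Neurod6, Crym and Egr3 (at least 2.77, 3.58 and 4.21 lower) and against striatum for Gpr6, Ankrd63 and Ido1 (at least 4.37, 5.53 and 3.54 lower) and for Crym. These lower limits allow for unmeasured values in the dim group, but not for the spread between arrays. Where arrays of the other group also lay below 5.18, their values entered its mean as read, and the limit is approximate. Limma with Benjamini-Hochberg adjustment placed 5165 of 11741 genes past an adjusted p of 0.05 between striatum and frontal cortex (2408 higher and 2757 lower in striatum). Between midbrain and frontal cortex it called 6026 genes, 3260 of them higher in midbrain. Between midbrain and striatum it called 6835, with 3918 higher in midbrain. The 10 genes named for each pair of regions stayed past the threshold under every alternative setting run and with each array left out in turn.

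In the striatum, the called rises in MPTP animals included astrocytic genes and the called falls included genes induced by neuronal activity. Of the 95 falls, 57 were of genes called higher in saline frontal cortex than in saline striatum. Whether the falls arose in striatal cells was not tested. The small GTPase Rras2 rose from 4.83 ± 0.16 to 6.62 ± 0.18 (n = 3), a log2 change of 1.79 with a standard error of 0.13, and of at least 1.44 since all its saline striatal values lay below the filter value of 5.18. The astrocytic intermediate filament genes Gfap and Vim rose by 1.17 and 1.01 on the log2 scale, or 2.25-fold and 2.01-fold. The early growth response gene Egr2, induced by neuronal activity, fell by 1.55 (SE 0.37), a 2.93-fold decrease. Limma called 247 of the 11741 genes, 152 higher and 95 lower, with 1912 at an unadjusted p under 0.05 where 587.1 would come by chance. The largest called rises included Cnksr3 (log2 change 1.73), Cemip2 (1.35), the cytokine receptor Osmr (0.97), the endothelial von Willebrand factor gene Vwf (0.93), the node of Ranvier adhesion gene Nfasc (0.88), the myelin tight-junction gene Cldn11 (0.88), Strip2 (0.87), the lysozyme gene Lyz2 (0.84) and Mid1 (0.83). Their adjusted p ran from 1.08e-08 for Rras2 to 0.0369 for Vwf. The largest falls after Egr2 were those of Ccn3 (-0.93), Cpne9 (-0.82), Mfsd4a (-0.81), the metabotropic glutamate receptor Grm8 (-0.76), Egr4 (-0.75), Slc17a6 (-0.74), the steroid-converting enzyme Hsd11b1 (-0.74), Car10 (-0.69), Ablim3 (-0.68), Ndn (-0.67) and Magi1 (-0.66). All saline values and 1 MPTP value of Osmr, and all MPTP values of Ablim3 and Slc17a6, lay below the filter value. The limits were a rise of 0.31 for Osmr, which is approximate, a fall of at least 0.28 for Ablim3 and none for Slc17a6. Without MPTP replicate 1, 3 of these falls were smaller and not called, Ccn3 at -0.60, Mfsd4a at -0.52 and Car10 at -0.44. Of the 4 other probe sets of Magi1, 3 gave -0.41 (unadjusted p = 0.0244), -0.25 and -0.15, and 1 gave 0.22 (unadjusted p = 0.176). Other probe sets above the filter value gave 0.45 (unadjusted p = 0.00337) and 0.08 (unadjusted p = 0.369) for Nfasc, -0.28 (unadjusted p = 0.0471) and -0.03 (unadjusted p = 0.871) for Mfsd4a, and -0.21 to -0.60 for Ndn. Of the 95 lower genes 57 (60%) were called higher in saline frontal cortex than in saline striatum, against 25 (16.4%) of the 152 higher genes and 2757 (23.5%) of all tested genes, a count chosen after seeing the data that shares the saline striatal arrays with the MPTP comparison. Nrn1, one of the genes highest in cortex over striatum, stood at 5.63 to 7.88 in MPTP striatum, at 7.57 to 8.41 in saline striatum and at 11.55 in saline cortex (adjusted p = 0.0554 for MPTP striatum).

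Quantile normalization of the striatal and other arrays a second time raised the striatal count to 745 genes, 359 higher and 386 lower, and 243 of the 247 genes were among them. Without the saline array of lowest interquartile range in each region, a setting chosen after seeing the data, 223 striatal genes were called and 144 of them were lower. With the mean over the probe sets of a gene 134 genes passed and 18 of 48 named striatal genes lost their call, and without an intensity trend 162 passed and 19 of 51 lost it. Leaving out 1 striatal array at a time gave 69 genes without MPTP replicate 1, 89 without saline replicate 2, 111 without saline replicate 3, 119 without saline replicate 1 (49 higher and 70 lower), 150 without MPTP replicate 3 and 291 without MPTP replicate 2. Of the 51 called striatal genes selected for naming, 33, 23, 30, 22, 19 and 10 lost their call in these fits, in that order. Rras2, Cnksr3, Cemip2, Gfap, Vim, Nfasc, Cldn11, Strip2, Grm8, Magi1, Ugt8a, Tspan2 and Olig1 kept theirs in all 6.

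Of 25 measured members of the microglia list 9 rose in MPTP striatum and none fell (18 and 0 when adjusted over the list alone), with Ly86 up by 0.63, the complement gene C1qa by 0.60, Gpr34 by 0.55 and the fractalkine receptor Cx3cr1 by 0.48. The median change of the list was 0.364 (camera adjusted p = 4.8e-17, and adjusted p = 0.471 with an estimated correlation). In the list of microglial activation genes 2 of 16 rose, Lyz2 and the MHC class I light chain B2m (0.38), and 8 when adjusted over the list alone. Its camera adjusted p was 2.57e-07 (adjusted p = 0.474 with an estimated correlation). Reactive astrocyte genes gave 6 rises among 23 members, or 8 when adjusted over the list alone, with Serpina3n up by 0.66 beside Gfap, Vim and Osmr. The test of this list gave a camera adjusted p = 1.54e-06, and adjusted p = 0.474 with an estimated correlation. The astrocyte list had 4 rises among 17 members (6 when adjusted over the list alone), in the gap junction genes Gjb6 (0.73) and Gja1 (0.51), the water channel Aqp4 (0.35) and glutamine synthetase Glul (0.31, and 0.20 and not called without striatal MPTP replicate 3). Its median of 0.167 gave a camera adjusted p = 2.57e-07, and adjusted p = 0.474 with an estimated correlation.

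Among 25 measured members of the oligodendrocyte and myelin list 6 rose in MPTP striatum and none fell (8 and 0 when adjusted over the list alone), including Cldn11, the galactolipid enzyme Ugt8a (0.76), Tspan2 (0.56) and the myelin glycoprotein gene Mag (0.41). The median change was 0.115 (camera adjusted p = 9.34e-06, and adjusted p = 0.656 with an estimated correlation). The precursor list had 1 rise among 12, in the lineage transcription factor Olig1 (0.43), against 3 rises and 1 fall when adjusted over the list alone. Camera gave that list an adjusted p = 0.0372, and adjusted p = 0.656 with an estimated correlation. Endothelial genes had 3 rises among 19 (4 rises and 1 fall when adjusted over the list alone), in Vwf, Sox17 (0.69) and the transporter Slco1a4 (0.44). Their camera adjusted p was 0.0092 (adjusted p = 0.656 with an estimated correlation). A second probe set of Sox17 gave -0.00, with an unadjusted p = 0.987.

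Of the 29 immediate early genes measured in striatum 4 fell and none rose (11 and 1 when adjusted over the list alone, where Egr3 was the rise), Egr2 and Egr4 together with Egr1 (-0.55) and Gadd45g (-0.53). The list median of -0.435 gave a camera adjusted p = 1.39e-06, and adjusted p = 0.656 with an estimated correlation. Of 25 synaptic vesicle and release genes 3 fell and none rose (6 and 0 when adjusted over the list alone), namely syntaxin Stx1a (-0.53, and -0.35 and not called without striatal MPTP replicate 1), Rph3a (-0.42) and synapsin Syn1 (-0.33), with a camera adjusted p = 0.0125 and adjusted p = 0.728 with an estimated correlation. A second probe set of Rph3a gave -0.14 (unadjusted p = 0.375). Stx1a, Rph3a and Syn1 stood at 9.43, 9.37 and 10.47 in saline striatum and at 11.54, 10.19 and 11.39 in saline frontal cortex. Of 17 cortical glutamatergic neuron genes measured in MPTP striatum none passed under either adjustment, and 13 lay lower and 4 higher, among them Slc17a7 at -1.22 (adjusted p = 0.215), Neurod6 at -0.63 (adjusted p = 0.28) and Neurod2 at -0.55 (adjusted p = 0.1). The median of this cortical list was -0.229 (camera adjusted p = 0.0648, and adjusted p = 0.728 with an estimated correlation). Among 17 cholesterol synthesis genes the regulator Srebf2 fell by 0.30 (a second probe set gave -0.17, unadjusted p = 0.103), and 5 fell when adjusted over the list alone (camera adjusted p = 0.0057, and adjusted p = 0.67 with an estimated correlation). No member of the 33 complex I subunits passed, and 0 passed when adjusted over the list alone, although the list as a whole lay lower with a median of -0.101 (camera adjusted p = 0.00109, and adjusted p = 0.728 with an estimated correlation). The 32 proteasome genes had no called member and 2 falls when adjusted over the list alone (camera adjusted p = 0.0497, and adjusted p = 0.887 with an estimated correlation).

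The 5 remaining lists past the camera threshold in striatum lay higher. In the glucocorticoid response list, the metallothionein gene Mt2 rose by 0.56 and Glul by 0.31 (0.20 and not called without striatal MPTP replicate 3), making 2 of 28 (9 rises and 1 fall when adjusted over the list alone), with a camera adjusted p = 0.0016 and adjusted p = 0.656 with an estimated correlation. In the circadian clock list Dbp rose by 0.42 and Arntl fell by 0.51, while 17 of its 19 members did not pass and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00502, and adjusted p = 0.656 with an estimated correlation). In the metallothionein and metal handling list Mt2 and ceruloplasmin Cp (0.53) rose among 11, against 4 when adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.656 with an estimated correlation). Among 16 interferon response genes Ifitm3 alone rose, by 0.72, under both adjustments, and 15 did not pass (camera adjusted p = 0.0348, and adjusted p = 0.67 with an estimated correlation). None of 29 ribosomal protein genes passed and 2 rose when adjusted over the list alone, with a list median of 0.0726 (camera adjusted p = 6.44e-05, and adjusted p = 0.67 with an estimated correlation).

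**Figure D1:**
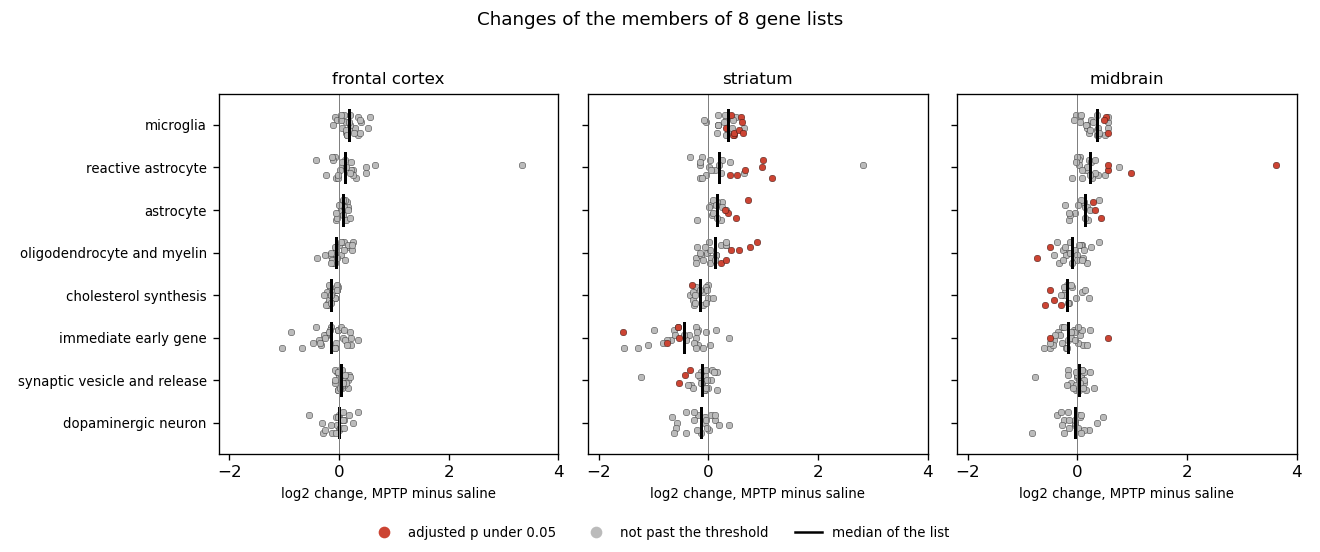
Log2 change between MPTP and saline animals (horizontal axis) for each measured member of 8 gene lists in the 3 regions, n = 3 arrays per group; red points have an adjusted p under 0.05, grey points do not, and the black bar is the median of the list. In striatum the microglia list has a median of 0.364 and the immediate early gene list one of -0.435.

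In the midbrain, the iron-binding acute-phase protein gene Lcn2 rose, with a difference of 3.63 between the mean log2 values (SE 0.89, adjusted p = 0.0296). Its saline midbrain values, 3.59 to 3.81, lay below the filter value of 5.18 and were not shown to be above background. The rise is given without a fold, as 2.13 from the filter value, an approximate limit since 1 MPTP value lay below it too. Interferon-induced membrane protein genes rose together with it, Ifitm1 by 1.08 (from 6.64 ± 0.15 to 7.72 ± 0.22, n = 3), Ifitm2 by 0.92 and Ifitm3 by 0.91. The cholesterol synthesis enzyme Mvd fell by 0.59 from 6.87 ± 0.24 to 6.28 ± 0.18 (n = 3). Limma called 298 genes, 253 higher and 45 lower, and 1952 had an unadjusted p under 0.05. Other large rises by the values were those of Lrg1 (1.91), the lipid droplet gene Plin4 (1.23), Tspyl1 (1.03), the lipopolysaccharide co-receptor Cd14 (0.98), Pdgfd (0.94), the lysozyme genes Lyz1 (0.89) and Lyz2 (0.85), and the kainate receptor Grik3 (0.83). A second probe set of Grik3 gave -0.13 (unadjusted p = 0.317), and one of Tspyl1, above the filter value, gave 0.02 (unadjusted p = 0.854). All saline midbrain values of Lrg1, Plin4, Cd14, Pdgfd and Grik3 lay below the filter value, and their limits were 0.18, 0.95, 0.63, 0.63 and 0.13. For Lrg1 and Grik3 1 MPTP value each lay below it too. Their SEs, 0.35 and 0.20, exceeded their limits, which therefore bound nothing. The largest falls were those of Rgs16 (-1.11), the hypothalamic peptide precursor Pmch (-1.10), Tnnt1 (1.998-fold lower), the glycine receptor Glra1 (-0.84), butyrylcholinesterase Bche (-0.75), the oligodendrocyte membrane gene Opalin (-0.74), Car4 (-0.73), Mlip (-0.71), Rasd1 (-0.71), Pdlim2 (-0.63) and Serpinb1a (-0.57). Of these, Glra1 lay below the filter value on all MPTP midbrain arrays (a fall of at least 0.54) and Mlip on all 6 midbrain arrays (no limit). Saline replicate 1 stood apart for 3 of these genes, at 7.51 for Rgs16 (5.96 and 6.20 in the other saline arrays of midbrain) and 7.48 for Pmch (5.64 and 5.49), and it was the highest array for Tnnt1 too. Without it Rgs16 differed by -0.64 and Tnnt1 by -0.56, both still called, and Pmch by -0.46, not called. Plin4 stood at 0.81 without MPTP replicate 1 and Glra1 at -0.52 without saline replicate 3, neither called.

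The midbrain count depended on single arrays more than the striatal one. It was 12 without MPTP replicate 3, 87 without saline replicate 3, 119 without saline replicate 2 (50 higher and 69 lower), 135 without MPTP replicate 1, 247 without MPTP replicate 2 and 955 without saline replicate 1. Of the 37 called midbrain genes selected for naming, 34, 23, 17, 24, 4 and 2 lost their call in these fits, in that order, and Ifitm1, Tspyl1 and Mlip kept theirs in all 6. Quantile normalization a second time gave 728 genes, 403 higher and 325 lower, with 289 of the 298 among them. With the mean over the probe sets of a gene 68 genes passed (58 higher and 10 lower) and 26 of 34 named midbrain genes lost their call, and without an intensity trend 153 passed and 18 of 37 lost it. Without the saline array of lowest interquartile range in each region, chosen after seeing the data, 111 genes passed, 44 higher and 67 lower, and 21 of the 37 named genes lost their call.

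The microglia list had 3 rises among 25 measured members and no fall in MPTP midbrain (13 and 0 when adjusted over the list alone), in Fcrls (0.57), C1qa (0.53) and Cd53 (0.48), with a median of 0.353 (camera adjusted p = 5.02e-07, and adjusted p = 0.654 with an estimated correlation). Of 16 microglial activation genes Lyz2 and Cd14 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.00247, and adjusted p = 0.868 with an estimated correlation). Reactive astrocyte genes had 4 rises among 23, or 8 when adjusted over the list alone, in Lcn2, Cd14, the glucocorticoid-induced co-chaperone Fkbp5 (0.56) and Serpina3n (0.56). Camera gave this list an adjusted p = 0.000199, and adjusted p = 0.654 with an estimated correlation. Gfap itself differed by 0.26 (SE 0.15, adjusted p = 0.388) and did not pass. The glucocorticoid response list had 5 rises among 28 (9 rises and 1 fall when adjusted over the list alone), with Plin4, Lcn2, Fkbp5 and Glul (0.33, and 0.08 with an unadjusted p = 0.496 for a second probe set) among them, a camera adjusted p = 0.0373 and adjusted p = 0.868 with an estimated correlation. Of 11 metallothionein and metal handling genes 0 passed, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0483, and adjusted p = 0.868 with an estimated correlation). Among 37 subunits of mitochondrial complexes II to V Atp5pb rose by 0.39 (0.05 with an unadjusted p = 0.498 for a second probe set), under both adjustments the only one, and the list median was 0.107 (camera adjusted p = 0.0165, and adjusted p = 0.954 with an estimated correlation). None of 29 ribosomal protein genes passed under either adjustment (camera adjusted p = 0.0234, and adjusted p = 0.954 with an estimated correlation).

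Cholesterol synthesis genes had 4 falls among 17 measured members and no rise (8 and 0 when adjusted over the list alone) in midbrain, in Mvd, Lss (-0.50), Dhcr7 (-0.43) and Hmgcs1 (-0.31). The list median was -0.188 (camera adjusted p = 1.46e-06, and adjusted p = 0.654 with an estimated correlation). Of the 4 other Hmgcs1 probe sets, those lower gave -0.37 (unadjusted p = 0.00131) and -0.12 (unadjusted p = 0.326), and those higher gave 0.14 (unadjusted p = 0.255) and 0.02 (unadjusted p = 0.857). Those of Lss gave -0.04 (unadjusted p = 0.803) and, below the filter value, 0.09 (unadjusted p = 0.471). Glra1 fell among 9 cerebellar and pontine genes, with 2 falls when adjusted over the list alone, a median of -0.365, a camera adjusted p = 0.000629 and adjusted p = 0.195 with an estimated correlation. Rgs16 fell among 9 midbrain and thalamic glutamatergic genes, with 3 falls when adjusted over the list alone, a median of -0.348, a camera adjusted p = 0.0057 and adjusted p = 0.654 with an estimated correlation. In the oligodendrocyte and myelin list Opalin and Ppp1r14a (-0.51) fell and 23 of 25 members did not pass, against 3 rises and 5 falls when adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.868 with an estimated correlation). Among 29 immediate early genes Gadd45g fell by 0.50 and Egr3 rose by 0.56, under both adjustments (camera adjusted p = 0.0409, and adjusted p = 0.954 with an estimated correlation). A second probe set of Egr3 gave -0.39 (unadjusted p = 0.00733), and the one used lay below the filter value on all saline and 2 MPTP arrays of midbrain.

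The dopaminergic markers were examined for every animal, since MPTP acts on these neurons. Tyrosine hydroxylase Th, the rate-limiting enzyme of dopamine synthesis, stood at 8.84 ± 0.18 in saline and 8.03 ± 0.08 in MPTP midbrain (n = 3), a difference of -0.82 (SE 0.29, 1.76-fold). The MPTP and saline midbrain arrays did not overlap for Th, which chance gives, in either direction, for 10% of genes in comparisons of 3 with 3, and limma gave an unadjusted p of 0.0089 and an adjusted p = 0.133, so that Th did not pass. The dopamine transporter Slc6a3 differed by -0.37 (SE 0.15, adjusted p = 0.208), the vesicular transporter Slc18a2 by -0.23 (SE 0.20, adjusted p = 0.594) and Ddc by -0.05 (SE 0.14, adjusted p = 0.913). A second probe set of Ddc, with a mean of 3.57 and so below the filter value, differed by -0.44 (unadjusted p = 0.00698). The sign for Ddc turned, at 0.06 and 0.01, without midbrain saline replicate 1 and without MPTP replicate 2, and with array weights. The SE of 0.29 for Th rests on 1 spread estimated over all 6 groups, not on the midbrain arrays alone. With only the 6 midbrain arrays in the limma fit, the adjusted p of Th was 0.000113. Its call thus depended on which arrays gave the spread. Over the alternatives run with 1 value per gene the adjusted p lay between 2.14e-08 and 0.373. None of the 21 measured dopaminergic neuron genes passed in midbrain under either adjustment (median change -0.0457, camera adjusted p = 0.195), nor any of 9 genes of dopamine synthesis, storage and uptake (median -0.0474, camera adjusted p = 0.3). Members of the first list that entered through another region, such as Neurod6 (2.76 to 3.37 in saline midbrain), cannot show a fall there. In striatum, where dopaminergic axons end, Th differed by -0.40 (adjusted p = 0.515), Slc6a3 by -0.19 (adjusted p = 0.582), Slc18a2 by 0.12 (adjusted p = 0.82) and Ddc by 0.37 (adjusted p = 0.192). On the striatal arrays Slc6a3 (3.70 to 4.32) and Slc18a2 (4.41 to 4.98) lay below the filter value throughout, and Th on 1 MPTP array, so that the striatal values of Slc6a3 and Slc18a2 decide nothing.

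**Figure D2:**
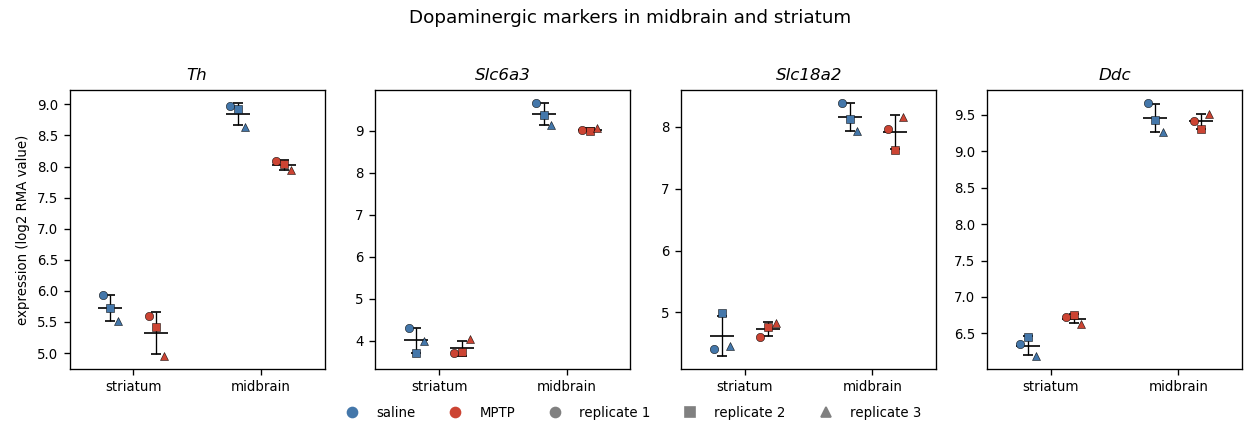
Log2 expression of Th, Slc6a3, Slc18a2 and Ddc (vertical axes) on each striatal and midbrain array; saline arrays are blue and MPTP arrays red, symbols mark the replicate number, dashes the group mean and bars the SD (n = 3). In midbrain Th averages 8.84 in saline and 8.03 in MPTP animals.

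The frontal cortex, which lies outside the nigrostriatal pathway, had few called genes. The transporter Slc47a1 fell from 6.01 ± 0.07 to 5.11 ± 0.27 (n = 3), by 0.90 on the log2 scale, and Bche fell by 0.74. The largest rises were those of Kctd8 (0.72), the phospholipid flippase Atp8a1 (0.63, from 10.46 ± 0.03 to 11.09 ± 0.02, n = 3), Wipf3 (0.56), the mitochondrial biogenesis coactivator Ppargc1a (0.55), the long non-coding RNA Malat1 (0.54) and the casein kinase gene Csnk2a1 (0.52). The saline cortex values of Kctd8 and the MPTP values of Bche lay below the filter value of 5.18, for a rise of at least 0.44 and a fall of at least 0.37. Limma called these 8 genes, 6 higher and 2 lower, with adjusted p from 0.0381 to 0.0487, and 720 genes had an unadjusted p under 0.05. Of the 6 other Malat1 probe sets, 3 gave 0.80 (unadjusted p = 7.01e-07), 0.73 (unadjusted p = 2.86e-06) and 0.65 (unadjusted p = 5.94e-06), and the remaining 3 gave 0.06, 0.05 and -0.07. Those of Ppargc1a gave 0.19, 0.18, 0.12 and -0.02, those of Atp8a1 0.41 (unadjusted p = 0.0148), 0.06, 0.04, 0.02, -0.02 and -0.10, and the single one of Kctd8 -0.03. Without MPTP replicate 2 the cortical count was 1, and without any other single array it was 0, as it was by limma without an intensity trend. It was 1 with the mean over the probe sets of a gene, where none of 7 named genes kept its call. With only the 6 cortical arrays it was 36 (33 higher and 3 lower), with array weights 14 (9 higher and 5 lower). Dnajb14 (0.51, adjusted p = 0.068) and Map1b (0.57, adjusted p = 0.0798) came next and did not pass, nor did Gfap (0.32, SE 0.15, adjusted p = 0.802).

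No member of a gene list passed in frontal cortex over all genes, while 10 of the 43 lists passed by camera. All 17 cholesterol synthesis genes lay lower in MPTP cortex, with a median of -0.146, and 2 passed when adjusted over the list alone, Hmgcs1 (-0.21) and Fdft1 (-0.19). Camera gave an adjusted p = 5.13e-10, and adjusted p = 0.269 with an estimated correlation. The pericyte, smooth muscle and meningeal fibroblast list had a median of -0.197 over 21 members, with 7 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.13e-10, and adjusted p = 0.0932 with an estimated correlation). Examples were the meningeal transporter Slc13a4 (-0.57), collagen Col3a1 (-0.58), the smooth muscle gene Tagln (-0.46) and the pericyte channel subunit Abcc9 (0.59). Microglial markers lay higher, with a median of 0.171 over 25 members and 1 past when adjusted over the list alone, Cx3cr1 (0.35), at a camera adjusted p = 7.28e-05 and adjusted p = 0.701 with an estimated correlation. The glucocorticoid response list had a median of 0.171 over 28 members and 3 higher when adjusted over the list alone, Fkbp5 (0.65), Lcn2 (3.34, from saline values below the filter value) and Mt2 (0.40), at a camera adjusted p = 0.0497 and adjusted p = 0.838 with an estimated correlation. The 11 metallothionein and metal handling genes had a median of 0.12 and 0 past when adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.594 with an estimated correlation). Egr2 differed by -0.88 among 29 immediate early genes, with 0 past when adjusted over the list alone and a median of -0.146 (camera adjusted p = 0.00104, and adjusted p = 0.838 with an estimated correlation). The remaining 4 lists lay lower: 7 hypothalamic genes with Pomc at -0.41 (camera adjusted p = 0.000315, and adjusted p = 0.0649 with an estimated correlation), and 4 genes of indirect pathway spiny neurons with Drd2 at -0.55 (camera adjusted p = 0.0127, and adjusted p = 0.246 with an estimated correlation), each with 1 lower when adjusted over the list alone. Saline cortex values of Drd2 (4.53 to 5.12) and of Gpr6 in the same list (3.27 to 4.02) lay below the filter value. A fall of these genes is thus not measured in cortex. The 33 complex I subunits (camera adjusted p = 0.0138, and adjusted p = 0.838 with an estimated correlation) and 5 cholinergic genes (camera adjusted p = 0.0256, and adjusted p = 0.594 with an estimated correlation) had 0 past when adjusted over the list alone.

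Averaged over the 3 regions, Lcn2 was higher in MPTP animals, with a difference of 3.27 between the mean log2 values (SE 0.52, adjusted p = 0.000504). All its saline values, 3.38 to 3.81, and 3 MPTP values lay below the filter value of 5.18. The rise is therefore given without a fold, as 1.73 from the filter value, an approximate limit. The SE of 0.52 treats the arrays of an animal as nearly independent. With 1 mean per animal, a setting chosen after seeing the data, limma gave Lcn2 an adjusted p = 0.00588 (SE 0.62). Without moderation the SE over animals was 1.23, and the exact two-sided permutation p was 0.1, the smallest that 3 animals against 3 can give. Lrg1 rose by 1.42, Plin4 by 0.90, Vwf by 0.89 and Ifitm1 by 0.78. All saline values of Lrg1 and Plin4 lay below the filter value (rises of 0.17 and 0.51 from it). Among the MPTP values 3 of Lrg1 and 2 of Plin4 lay below it too, so that these limits are approximate. The choroid plexus transport protein Ttr fell by 1.22, the activity-induced Fos by 0.94 and Egr2 by 0.93. Ttr varied widely between the MPTP striatum arrays, as given below, and the labels do not say how much choroid plexus each piece held. Limma with the animal as a random block called 1061 genes, 776 higher and 285 lower. Other rises were those of Lyz1 (0.75), Osmr (0.74), the purine enzyme Xdh (0.74), Mid1 (0.73), Rras2 (0.71), Cd14 (0.70) and Lyz2 (0.70). For Osmr all saline values and 4 MPTP values lay below the filter value, with an approximate limit of 0.25. Other falls were those of Bche (-0.56), Klf2 (-0.55), the endothelial immediate early gene Apold1 (-0.52), Egr4 (-0.50), Tnnt1 (-0.49), Cep128 (-0.49), Opalin (-0.45), Gkn3 (-0.45) and Gadd45g (-0.43). With 1 mean per animal 787 genes were called, 733 of the 1061 among them, and Fos was not (adjusted p = 0.08). The mean over the probe sets of a gene ended the call of 3 of 22 named genes. The count was 424 without striatal saline replicate 2, 490 without striatal saline replicate 1, 658 without midbrain MPTP replicate 3 and 668 without cortical MPTP replicate 2. Without midbrain saline replicate 2 it was 1478, with 771 higher and 707 lower. Of the 24 genes named for the mean, 5 lost their call without striatal saline replicate 2, and 1 each without striatal saline replicate 1, striatal MPTP replicate 1, cortical saline replicate 3, cortical MPTP replicates 1 and 2, midbrain saline replicate 3 and midbrain MPTP replicates 1 and 2. Quantile normalization a second time gave 1984 genes, 914 higher and 1070 lower, and 1020 of the 1061 were among them. Without the saline array of lowest interquartile range in each region the count was 916, of which 569 were lower.

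Over the 3 regions 16 of 25 microglial genes rose and none fell (19 and 0 when adjusted over the list alone), with Cx3cr1 up by 0.39, C1qa by 0.50 and Fcrls by 0.44. The median change of this list was 0.303 (camera adjusted p = 2.49e-13, and adjusted p = 0.563 with an estimated correlation). Microglial activation genes had 6 rises among 16, or 9 when adjusted over the list alone (camera adjusted p = 4.11e-05, and adjusted p = 0.563 with an estimated correlation). Reactive astrocyte genes had 10 rises among 23, or 12 when adjusted over the list alone, Gfap at 0.58 and Vim at 0.45 among them (camera adjusted p = 2.1e-05, and adjusted p = 0.563 with an estimated correlation). The astrocyte list had 5 rises among 17 (10 rises and 1 fall when adjusted over the list alone), with Gjb6 at 0.41 and Gja1 at 0.30 (camera adjusted p = 0.000873, and adjusted p = 0.563 with an estimated correlation). Metallothionein and metal handling genes had 6 rises among 11 (6 rises and 1 fall when adjusted over the list alone), with Mt2 at 0.46 and Cp at 0.42 (camera adjusted p = 0.00904, and adjusted p = 0.563 with an estimated correlation). Glucocorticoid response genes had 12 rises and 1 fall among 28 (14 and 2 when adjusted over the list alone), at a camera adjusted p = 0.00403 and adjusted p = 0.563 with an estimated correlation. Cholesterol synthesis genes had 10 falls among 17 and no rise (11 and 0 when adjusted over the list alone), with Mvd at -0.36, Dhcr7 at -0.30 and Hmgcs1 at -0.20 (camera adjusted p = 2.21e-08, and adjusted p = 0.563 with an estimated correlation). Immediate early genes had 7 falls and 1 rise among 29 (11 and 1 when adjusted over the list alone), with Egr3, at 0.39, as the rise (camera adjusted p = 1.18e-05, and adjusted p = 0.563 with an estimated correlation).

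Ribosomal protein genes had 2 rises among 29 for the mean over regions, or 5 when adjusted over the list alone, with a median of 0.0527 (camera adjusted p = 0.00681, and adjusted p = 0.846 with an estimated correlation). Complex I subunits had 4 falls among 33 under both adjustments, Ndufc2 at -0.13 among them, with a median of -0.0412 (camera adjusted p = 0.0141, and adjusted p = 0.878 with an estimated correlation). None of 9 midbrain and thalamic glutamatergic genes passed under either adjustment, with a median of -0.223 (camera adjusted p = 0.0398, and adjusted p = 0.563 with an estimated correlation). The rotation test fry, which asks whether the genes of a list move on balance one way, passed 5 lists for the mean: microglia at an adjusted p = 0.0127, and microglial activation, reactive astrocyte, cholesterol synthesis and metallothionein genes at an adjusted p = 0.0177 each. It passed no list in a single region. Neither fry nor camera had a block by animal, so that for the mean they treated the 18 arrays of 6 animals as independent.

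**Figure D3:**
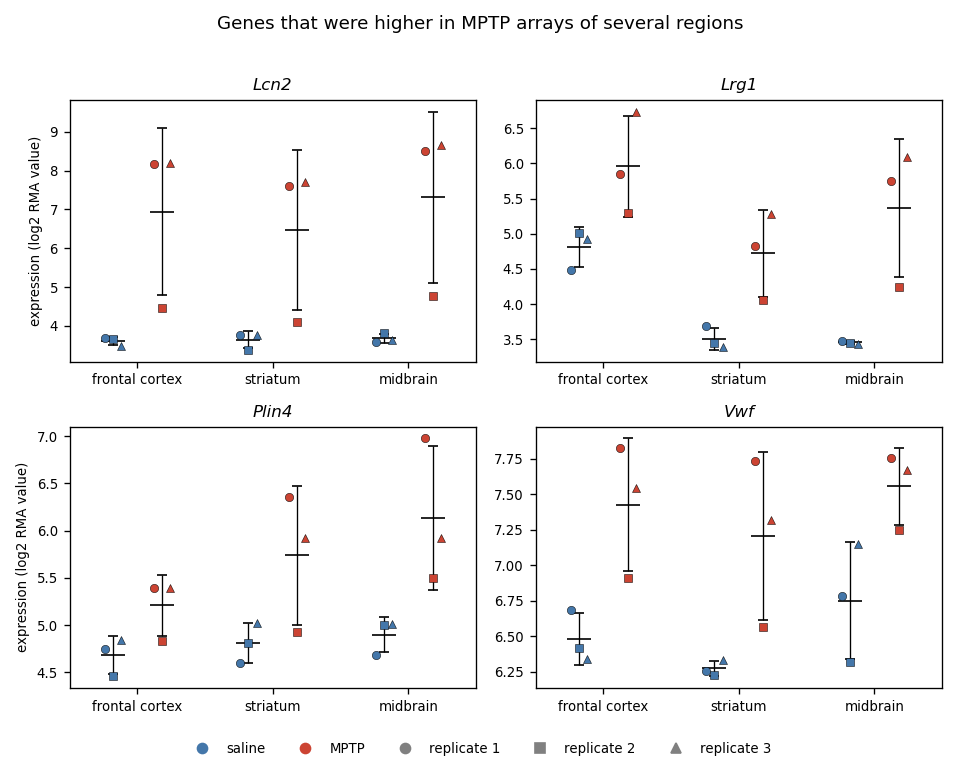
Log2 expression of Lcn2, Lrg1, Plin4 and Vwf (vertical axes) on each array of the 3 regions; saline arrays are blue and MPTP arrays red, symbols mark the replicate number, dashes the group mean and bars the SD (n = 3). Lcn2 stands between 3.38 and 3.81 on the saline arrays.

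Lcn2 differed between MPTP animals. Its saline values lay between 3.38 and 3.81 in the 3 regions. In MPTP replicates 1, 2 and 3 it stood at 8.18, 4.46 and 8.19 in frontal cortex, at 7.59, 4.11 and 7.71 in striatum and at 8.49, 4.78 and 8.66 in midbrain. All saline values and those of MPTP replicate 2 lay below the filter value of 5.18, so that the size of a difference is not measured there. In cortex and striatum the gene was not past the threshold, with differences of the mean log2 values of 3.34 (SE 0.89, adjusted p = 0.29) and 2.83 (SE 0.89, adjusted p = 0.0989). Without moderation the SE was 1.24 in cortex, 1.19 in striatum and 1.27 in midbrain. Vwf stood at 7.73, 6.57 and 7.32 in the striatum of MPTP replicates 1, 2 and 3, and Plin4 at 6.98, 5.50 and 5.92 in their midbrain. Fos stood at 7.19, 8.69 and 9.22 in frontal cortex, at 5.26, 7.50 and 7.62 in striatum and at 7.41, 8.56 and 8.89 in midbrain of the same replicates. Ttr ranged from 7.01 to 10.18 over the MPTP striatum arrays and from 10.14 to 10.61 over the saline ones.

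The same genes were called in striatum and midbrain more often than independent lists would share them. Of the 152 genes higher in striatum and the 253 higher in midbrain 49 were shared, where 3.28 would be for independent lists. Of the 95 and 45 lower genes 8 were shared, against 0.364. By the labels the regions came from the same 3 animals per treatment. Differences between these animals can therefore enter the lists of several regions, and the counts for independent lists do not allow for this. Shared rises included Lyz2, Mid1, Ifitm1, Ifitm3, Strip2, Tspyl1, Serpina3n and C1qa, and Gadd45g was a shared fall. Frontal cortex and striatum shared 3 rises, Atp8a1, Malat1 and Ppargc1a, against 0.0777, and frontal cortex and midbrain shared 1 fall, Bche, against 0.00767. The log2 changes of striatum and midbrain correlated at 0.517 across the 11741 genes, which are not independent replicates, where the other 9 splits of the animals by replicate gave -0.0658 to 0.311. For frontal cortex and striatum the correlation was 0.348 (other splits -0.209 to 0.213) and for frontal cortex and midbrain 0.432 (other splits 0.12 to 0.449).

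Whether the response to MPTP differed between regions was tested as an interaction. A small set of genes responded in striatum more than in frontal cortex, led by Cnksr3 (6.04 ± 0.23 to 7.77 ± 0.10 in striatum and 5.74 ± 0.12 to 5.84 ± 0.16 in cortex, n = 3), with a difference of 1.63 (SE 0.19, 3.09-fold). Rras2 differed by 1.47, Cemip2 by 1.15, Marcksl1 by 0.95, Fam107b by 0.86 and Nfasc by 0.74. The same test between midbrain and striatum gave -1.90 for Cnksr3, -1.78 for Rras2, -1.24 for Cemip2, -1.05 for the protease gene Adamts4, -0.89 for Nfasc and -0.68 for the deacetylase gene Sirt2, so that the striatal response was the higher one. Of 2 other probe sets of Nfasc, 1 gave 0.38 (unadjusted p = 0.0615) and -0.65 (unadjusted p = 0.00278) in the 2 tests, and the other 0.00 (unadjusted p = 0.978) and -0.19 (unadjusted p = 0.126). Adamts4 itself rose by 0.60 in striatum and fell by 0.45 in midbrain. Limma called 7 genes for striatum minus frontal cortex, all 7 higher, and 8 for midbrain minus striatum, all 8 lower. The predicted gene 9630013A20Rik, passed over by the naming rule and chosen after its values were seen, had the largest difference of the values in both tests, which share the striatal arrays. It stood at 4.15, 4.42 and 4.13 in saline striatum and at 7.38, 7.33 and 7.01 in MPTP striatum, a log2 change of 3.01 (SE 0.14, adjusted p = 8.23e-13), and at 3.62 to 4.22 on the frontal cortex arrays and 3.72 to 4.02 on the midbrain arrays. All but the MPTP striatum values lay below the filter value of 5.18, so that its striatal rise was at least 2.06 and its rank is that of the values alone. The same holds for the size of the Rras2 differences, since its saline striatal values lay below 5.18. Fam107b, the eighth gene of the second test and chosen in the same way, differed by -0.86.

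No gene passed for midbrain minus frontal cortex by limma, where 584 genes had an unadjusted p under 0.05. The smallest p there belonged to Mlip (-0.76, adjusted p = 0.268), Ebf3 (0.85, adjusted p = 0.268) and Glrb (0.67, adjusted p = 0.286), where other probe sets above the filter value gave 0.11 for Ebf3 and 0.33 for Glrb. Mlip lay below the filter value on all midbrain arrays, so that the size of its difference is not measured. Without midbrain saline replicate 1 the count for midbrain minus frontal cortex was 10, without midbrain saline replicate 2 it was 3, and with array weights it was 1. With the animal as a fixed block genes passed in both directions, as given below, on the assumption that a number marks the same animal in each region. For striatum minus frontal cortex the count was 3 without striatal MPTP replicate 1 and 3 without cortical MPTP replicate 3, and leaving out any 1 of the 12 arrays ended the call of 1 to 4 of the 6 named genes, but not of Cnksr3 or Rras2. The mean over the probe sets of a gene ended the call of 3 of 5 named genes for striatum minus cortex and of 1 of 5 for midbrain minus striatum. For midbrain minus striatum the count was 14 without midbrain saline replicate 1, and the 6 named genes kept their call with each of the 12 arrays left out. Quantile normalization a second time gave 21, 0 and 22 genes for striatum minus cortex, midbrain minus cortex and midbrain minus striatum (20 higher and 1 lower for the first, 4 higher and 18 lower for the last).

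**Figure D4:**
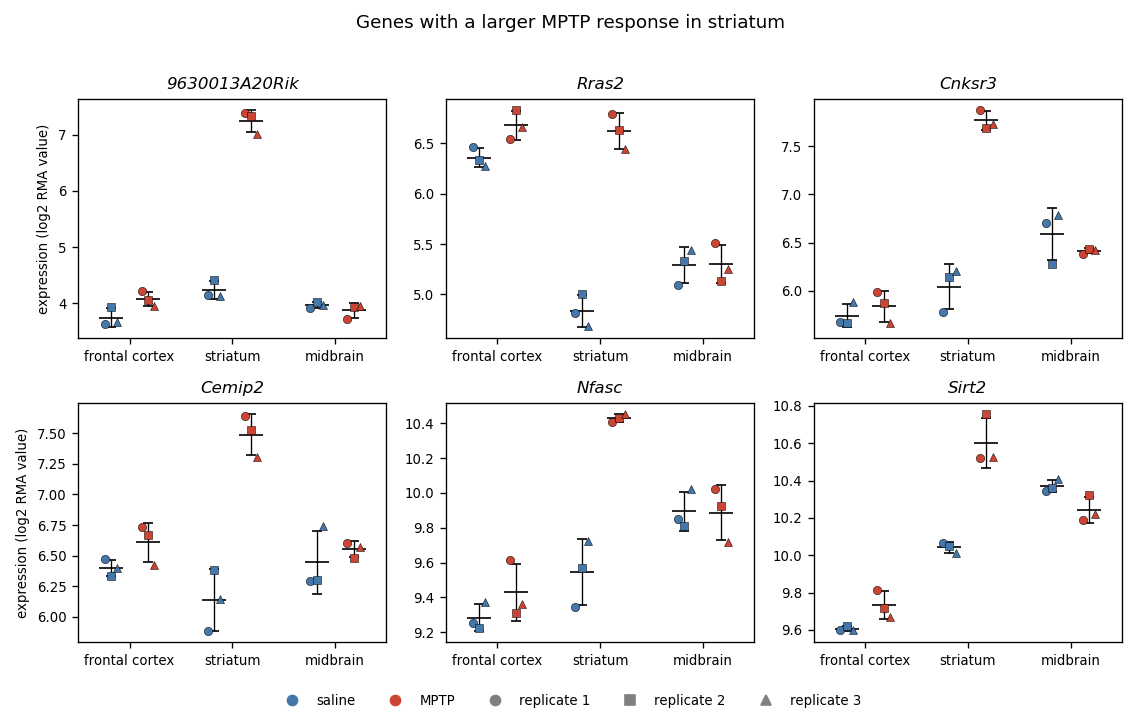
Log2 expression of 6 genes (vertical axes) whose MPTP response was higher in striatum than in frontal cortex or midbrain, on each array; saline arrays are blue and MPTP arrays red, symbols mark the replicate number, dashes the group mean and bars the SD (n = 3). On the striatal arrays 9630013A20Rik stands at 4.13 to 4.42 in saline and 7.01 to 7.38 in MPTP animals.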

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

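The tests of white matter, early oligodendrocyte genes, neutrophil genes, MPTP replicate 2 and the dopaminergic share were chosen after the results were seen, and the counts over other splits of the arrays were planned. Several replaced a first version after its result was seen. The white matter test was first a count of genes above every saline array (5 of the 7), that of early oligodendrocyte genes had another criterion, and that of the dopaminergic share used Slc6a3, Slc18a2 and Ddc alone (median -0.235). The test of MPTP replicate 2 first used percentages of called genes, then called genes with a log2 change of at least 1, whose median position in striatum was 0.401 (highest saline array 0.358) and in midbrain 0.39 (highest 0.981), before the 10 genes of smallest p. It and the neutrophil test were divided by region after their values were seen.

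The response to MPTP differed between striatum and frontal cortex for 7 genes by the interaction test, among them Cnksr3 (log2 difference 1.63), Rras2 (1.47), Cemip2 (1.15), Marcksl1 (0.95), Fam107b (0.86) and Nfasc (0.74). Between midbrain and striatum 8 genes differed, among them Cnksr3 (-1.90), Rras2 (-1.78), Cemip2 (-1.24), Adamts4 (-1.05), Nfasc (-0.89) and Sirt2 (-0.68).

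More white matter in the MPTP striatum pieces would raise mature myelin genes about as much as these 7 genes. The 25 measured oligodendrocyte and myelin list members outside the 7 had a median striatal change of 0.115 (SD 0.292), against 1.35 for the 7. The 7 were picked by their response on the same arrays, which can raise their median. The 6 abundant mature myelin genes had a median change of 0.324, and 4 of them were called, Mbp, Mag, Cnp and Cldn11. The list members thus rose by less than the 7. A lower median was likely from the start for any list set against genes picked for a higher striatal response. The comparison therefore does not decide, and white matter stays open as a source. Early oligodendrocyte genes outside the 7 had a median of 0.116 (SD 0.166), and 9 of 12 lay higher. Limma called 0 of the 12 over all genes, and 2 passed when adjusted over the list alone, Prom1 (0.41) and Frmd4a (0.35). Any early genes among the 7 were left out of this list by construction, so that it decides nothing and early stages stay open. A response of striatal cells to MPTP, the difference named by the design, stays open as a hypothesis. In 13 of 100 splits of the arrays, the real one among them, striatum minus cortex gave as many genes as the real 7, the highest other, 180, in the split that exchanged the treatment labels in 1 region and so adds the 2 responses up, and 11 of the rest gave as many, up to 97, so that these splits do not exclude chance for the count.

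Lcn2 was higher on every MPTP array than on every saline array of its region, and lower in MPTP replicate 2 than in the other MPTP replicates in each region. Neutrophil granule genes, all below the filter, had a median of 0.318 in frontal cortex (S100a8 0.58, S100a9 0.68, Camp -0.11, Ngp 0.06). The median was 0.13 in striatum (0.21, 0.57, -0.20 and 0.05 in that order) and 0.836 in midbrain (1.36, 1.48, -0.00 and 0.31). In midbrain limma without the filter gave unadjusted p of 5.74e-06 for S100a8, 1.4e-07 for S100a9, 0.99 for Camp and 0.0292 for Ngp. Since these genes did not reach the filter value, they do not decide, and neutrophils stay open in all 3 regions. If MPTP replicate 2 held RNA of a saline animal, the 10 genes of smallest p without its array would stand in it near the saline mean (0) and not the MPTP mean (1), but in striatum their median position was 0.859 (quartiles 0.593 and 1.01), against -0.112 to 0.112 for saline arrays left out in the same way (highest quartile 0.248), which argues against saline RNA on that array. In midbrain the position was 0.536, inside the -0.0564 to 0.592 of the saline arrays, and in frontal cortex 0.803 with 1 gene called, so that saline RNA is not excluded there by these genes. Of the genes called without the array 49.5% of 291 in striatum and 73.3% of 247 in midbrain lay on its MPTP side, against up to 31.1% and 76.3% for saline arrays, and a difference in response between animals stays open.

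Th was lower on each MPTP midbrain array than on each saline one, without passing the test. A smaller share of the dopaminergic nuclei in the MPTP pieces would lower other genes of these neurons by about as much as Th, which differed by -0.82 (SE 0.29). The 8 dopaminergic neuron genes other than Th that stood over 1 higher in saline midbrain than in both other regions, and 1 above the filter value, had a median change of -0.195 (SD 0.205), from -0.37 for Slc6a3 and -0.28 for Sncg to 0.12 for Chrna6 and 0.22 for Aldh1a1. As a set these genes were lower by less than Th, with 6 of the 8 lower. They were picked by region, and no values here show that they are confined to dopaminergic neurons, so that they do not decide the source of the difference in Th. A smaller share of the nuclei, a loss of neurons, and lower Th in the neurons that MPTP acts on stay open as hypotheses.

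Several gene lists shifted differently in striatum than in frontal cortex by camera, none of them with an estimated correlation, where the lowest adjusted p was 0.131. The median difference was 0.111 for astrocyte, 0.161 for cholinergic, 0.0594 for ribosomal protein, 0.29 for hypothalamic, 0.0601 for interferon response, 0.355 for indirect pathway spiny neuron, 0.191 for microglia and 0.14 for microglial activation genes. It was 0.103 for oligodendrocyte and myelin, 0.289 for pericyte, smooth muscle and meningeal, and 0.0394 for reactive astrocyte genes, and it was -0.301 for cortical glutamatergic, -0.27 for immediate early and -0.17 for synaptic vesicle genes. Of the indirect pathway genes, Drd2 and Gpr6 lay below the filter value on all saline cortex arrays, so that their cortical change is not measured.

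For midbrain minus frontal cortex the lowest adjusted p with an estimated correlation was 0.307. The median differences were 0.168 for GABAergic interneuron, -0.327 for cerebellar and pontine, 0.0678 for ribosomal protein, 0.111 for heat shock, 0.193 for direct and 0.234 for indirect pathway spiny neuron genes. They were 0.101 for microglia, 0.0956 for microglial activation, 0.0817 for complexes II to V, 0.283 for pericyte, smooth muscle and meningeal, and 0.126 for reactive astrocyte genes. The cortical change of Drd2 and Gpr6, in the indirect pathway list, is not measured here either. For midbrain minus striatum the lowest was 0.0632. The median differences were -0.0691 for astrocyte, -0.479 for cerebellar and pontine, -0.0999 for cholesterol synthesis, -0.0809 for clock, 0.276 for immediate early, -0.0601 for microglia and -0.411 for midbrain and thalamic glutamatergic genes. They were 0.101 for complex I, 0.126 for complexes II to V, -0.17 for oligodendrocyte and myelin, -0.12 for oligodendrocyte precursor, 0.0946 for proteasome and 0.146 for synaptic vesicle genes.

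Probe sets that named several genes or were not listed with a gene entered no comparison of genes. Of 3214 such probe sets tested, 4 passed in frontal cortex, 44 in striatum (38 higher and 6 lower) and 119 in midbrain (108 higher and 11 lower).

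With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes in frontal cortex (8, highest other 1), striatum (247, highest other 24), midbrain (298, highest other 1), for the mean over regions (1061, highest other 4) and for each pair of saline regions (5165, 6026 and 6835, highest other 0). For midbrain minus striatum 9 of 100 splits, the real one among them, gave as many as the real 8, the highest other 305, which does not exclude chance for the count. For midbrain minus frontal cortex limma called 0 genes, with 584 at an unadjusted p under 0.05. All 100 splits gave at least as many, the highest other 687, an outcome that a count of 0 fixes and that decides nothing. The treatment labels are mixed within a region in such splits, so that the response to MPTP enters their counts, and whether another structure of the samples raised them was not tested.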

How the results depend on the processing

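The interquartile range as a covariate, the fit without the saline array of lowest interquartile range in each region, 1 mean over the regions per animal, and every probe set on its own were chosen after the data were seen, and all other settings were planned. In the settings with 1 value per gene, no gene named in the text turned its direction in a comparison where it was called. Probe sets on their own did not enter this check. Of 118 other probe sets of genes named in a single region 96 had the same sign. One of Egr3 in midbrain had the opposite sign (-0.39, unadjusted p = 0.00733 by limma). Over 3314 values under settings other than leaving out 1 array, 2925 stayed past the threshold and 389 lost the call. Over 2946 values with 1 array left out 2380 stayed and 566 lost it. These counts include the 10 genes named for each pair of saline regions, which kept every call, so that the share kept is lower for the MPTP comparisons alone. Of 664 values of named genes that were not called, 32 passed and 3 turned sign, those of Ddc in midbrain, at 0.0388 with array weights, 0.0571 without midbrain saline replicate 1 and 0.0051 without midbrain MPTP replicate 2, in a range of -0.1403 to 0.0571 over the arrays left out. The cause of the moves listed here was not tested, except where fewer genes or arrays entered by construction. What follows gives counts of called genes.

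Without a filter striatum minus cortex gave 4. At the 75th percentile, with fewer genes tested, frontal cortex gave 5, striatum minus cortex 0 by limma and midbrain minus striatum 3. Quantile normalization a second time gave 4 in frontal cortex, 745 in striatum, 728 in midbrain, 1984 for the mean, 21 for striatum minus cortex and 22 for midbrain minus striatum. Median centring gave 2 in frontal cortex. The mean over the probe sets of a gene gave 1 in frontal cortex, 134 in striatum, 68 in midbrain, 4 for striatum minus cortex, and 7 gene lists for the mean. Limma without a trend gave 0, 162 and 153 in the 3 regions. Array weights gave 14, 487 and 833 in the regions, 1783 for the mean, and 24, 1 and 23 for striatum minus cortex, midbrain minus cortex and midbrain minus striatum. The 6 arrays of frontal cortex alone gave 36.

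The covariate gave 0, 711 and 745 in frontal cortex, striatum and midbrain, 1612 for the mean, 24 for striatum minus cortex and 20 for midbrain minus striatum. Without the saline arrays of lowest interquartile range, frontal cortex gave 0 by limma, midbrain 111, striatum minus cortex 4, midbrain minus striatum 13, and 6 gene lists passed for midbrain minus cortex. Every probe set on its own, with 23992 tested, gave 21, 470 and 978 in the regions, 2595 for the mean, 14 for striatum minus cortex, 14 for midbrain minus striatum, and 10184, 11444 and 13279 for the saline regions. Camera with an estimated correlation passed 0 lists in all 7 contrasts, and fry 0 in 6 of them and 5 for the mean.

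Leaving out 1 array gave 0 to 1 gene in frontal cortex, 69 to 291 in striatum, 12 to 955 in midbrain, 424 to 1527 for the mean, 3 to 10 for striatum minus cortex, 0 to 10 for midbrain minus cortex and 7 to 14 for midbrain minus striatum. For the saline regions it gave 4551 to 4733, 5497 to 6189 and 6279 to 6955. Where 2 arrays remained in a group, they were assumed to vary like the others.

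Replicate numbers do not mark animals shared by the treatments, and the labels do not say that they mark an animal across regions. The deviations of same-numbered arrays correlated at 0.225 to 0.342 between saline cortex and midbrain and at 0.117 to 0.183 between MPTP striatum and midbrain, where all 6 arrays correlated best with their own number, but at -0.202 to 0.141 between saline cortex and striatum, where 2 of 6 did. As a fixed replicate block in a region the number gave 417 genes in striatum, and the adjusted p of Th in midbrain was 2.14e-08. The animal as a fixed block over 2 regions gave 12 genes for striatum minus cortex (10 higher and 2 lower), 37 for midbrain minus cortex (19 and 18) and 29 for midbrain minus striatum (15 and 14). As a random block it ended no call of a named gene, and the mean over regions without the block gave 1081 genes. With 1 mean over the regions per animal it gave 787 (622 higher and 165 lower).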

Other observations

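The tests of this part were planned, and which lists to describe was decided after their values were seen. Genes of the unfolded protein and integrated stress response were called in midbrain, where 3 of 26 measured members rose and none fell (8 and 0 when adjusted over the list alone). The stress transcription factor Xbp1 rose by 0.59 (SE 0.12, adjusted p = 0.0127), the endoplasmic reticulum chaperone Hsp90b1 by 0.41 (SE 0.10, adjusted p = 0.0267) and calreticulin Calr by 0.32 (SE 0.08, adjusted p = 0.0399). The list itself did not pass by camera in midbrain (median 0.106, adjusted p = 0.0599, and adjusted p = 0.868 with an estimated correlation), and none of its members was called in striatum.

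Among 21 antioxidant and NRF2 response genes, catalase Cat and the microsomal glutathione transferase Mgst1 rose in both striatum (0.45 and 0.72) and midbrain (0.40 and 0.61), and no member fell in either region. When adjusted over the list alone 3 rose in striatum and 4 in midbrain, and camera gave an adjusted p = 0.667 and an adjusted p = 0.712. The stathmin family gene Stmn4 fell in striatum (-0.28) and midbrain (-0.36), while Marcks rose in striatum (0.46), among 21 axonal injury and outgrowth genes. The glucose transporter Slc2a1 rose in midbrain by 0.51, the single called member of 19 glycolysis genes there, and the leukemia inhibitory factor receptor Lifr rose in striatum by 0.44.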
